A study of Mus musculus with 2 samples.

How the data were processed

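Total RNA-seq libraries from the left cerebral cortex of 2 female B6CASTF1/J mice of 36 days were used, 1 library per mouse, both in 1 group. Group and replicate number come from the labels, which name a different animal for each library but share 1 donor record, read here as a record of the strain. Per the labels, 300 ng of RNA went into each library, libraries were stranded and reduced in ribosomal RNA, and ERCC spike-ins were added. The genome build is mm10 per the labels, and the annotation is GENCODE M21 per the deposited notes. The aligner, its settings, the strand setting of the counting and the software versions are not given in the sources used here. The column names of the tables are those that RSEM writes for the gene table and first transcript table, and those that kallisto writes for the second transcript table.

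Each library came with 3 tables. The gene table and the first transcript table hold, per the file headers, the expected count of each gene or transcript, its TPM and its FPKM, as computed by the authors, and the first transcript table also holds the percent of its gene's abundance each transcript takes. The second transcript table holds, per the file headers, an estimated count and a TPM from the authors' second quantifier. Expected counts divide a read among the genes or transcripts it fits, so genes with near-identical copies carry uncertain values. TPM in the deposited tables is scaled to a fixed total over all rows, including spike-ins and short abundant RNAs, so a large share of 7SL RNA lowers the TPM of every other gene. Reads were quantified against the C57BL/6J reference while the mice carry a CAST/EiJ allele of every autosomal gene, and any loss of reads from that allele was not tested.

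The gene table holds 81881 rows: 55536 annotated genes, 26248 rows named only by number, 96 spike-ins and 1 row for the phage phiX174, which had 0 counts. All 55536 gene identifiers matched the annotation, from which symbols, gene types and coordinates were taken. Rows named by number were left out of the comparisons. The first transcript table lists 141862 annotated transcripts and the second 141767.

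Replicate 1 held 29417200 and replicate 2 held 35188800 expected counts over all rows, each rounded to the nearest 100. Intervals are 95% exact Clopper-Pearson intervals of the share of a gene's reads that came from replicate 2, turned into log2 ratios with the TMM library sizes. Reads carry no molecular identifiers in these tables, so intervals and the floor of 3 counts cover counting error only.

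Levels are TPM as deposited, as mean ± SD of the 2 mice, and genes with a TPM of at least 1 in both libraries were counted as expressed. Ratios are log2 ratios of replicate 2 over replicate 1 in CPM (counts scaled to library size), from expected counts rounded to whole numbers, TMM library sizes (edgeR 4.0.16 in R 4.3.3) and a prior count of 2. Genes stood apart when their mean count was at least 100 and their ratio at least 2-fold, a rule of size with no test. The biological coefficient of variation is the square root of edgeR's common dispersion with an intercept only, over genes with a mean count of at least 10. A read-level test of 2 libraries would compare these libraries and not a condition, so none was run. Each of 39 fixed gene lists, 23 of cell type or region markers and 16 others, was summarised by its median TPM and its median log2 ratio. Lists with at least 3 genes of mean count 10 or more were placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 libraries only. Isoform shares are a transcript's TPM over its gene's. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and DESeq2 1.42.0 for its size factors.

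The genes named in the text were fixed by rule before the data were examined, as were the lists, pairs and alternatives: the 15 nuclear protein-coding genes and 5 noncoding genes with the highest mean TPM, the 10 genes with the largest ratio each way among genes with a mean count of at least 100, the members of the lists, and the fixed pairs and isoform genes. Exceptions are named where they appear, and some genes and pairs that the rule covers are not reported here by name, although counts over all genes, lists, pairs and isoforms include them.

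The steps were tested on simulated data made from the means and sizes of these libraries, with a dispersion of 0.01. Over 12623 genes, 100 genes changed 4-fold had a median log2 ratio of 2.02 and all 100 passed the 2-fold rule, and 100 genes changed 2-fold had a median of 0.99 and 49 passed. With no gene changed, 1 of 12623 genes passed. The simulation gave every gene the same dispersion and divided no reads among copies, while the coefficient of variation in the data was 12.3%. More unchanged genes could therefore pass in the data. A coefficient of variation of 10% was estimated as 10.0% over 18217 genes. Of 400 random lists of 16 genes, 25 lay outside the central 95% with no shift, and 297 with a log2 shift of 0.2.

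Alternatives were other scalings (DESeq2 size factors, total counts, upper quartile, spike-ins), other minimum levels and pseudocounts, FPKM, either transcript table, other random lists, and either mouse alone. For the check of GC content and length, a lowess curve with a span of 0.3 was fitted on 14542 protein-coding genes, using the GC content of each gene's most abundant transcript, known for 18176 of 18187 genes.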

Results

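Total RNA was sequenced from the left cerebral cortex of 2 female mice of the strain B6CASTF1/J, the first-generation cross of C57BL/6J and CAST/EiJ, at 36 days of age. The labels name a separate animal for each library and put both libraries in 1 group, so the series holds no treatment, second tissue or second age. Each library started from 300 ng of RNA, was reduced in ribosomal RNA, kept strand, and carried synthetic RNA spike-ins (the External RNA Controls Consortium set, ERCC). Replicate 1 held 29417200 expected counts and replicate 2 held 35188800, each rounded to the nearest 100. The design implies a description of which transcripts this cortex carried and at what level, and a comparison of the 2 mice. With 1 library per mouse no p-value was computed, and each mean ± SD below is over the 2 mice.

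Among nuclear protein-coding genes the highest mean level was that of Snap25, which encodes a protein of synaptic vesicle fusion, at 1291 ± 141 TPM (a length-corrected share of all transcripts; SD, n = 2). It was followed by Camk2a, the alpha subunit of calcium/calmodulin-dependent kinase II, at 1087 ± 126 TPM, the glycolytic enzyme gene Gapdh at 1079 ± 29.8 TPM and the imprinted gene Snurf at 1076 ± 22.4 TPM. The ferritin heavy chain gene Fth1 stood at 1063 ± 42.0 TPM and Nrgn, which encodes the calmodulin-binding protein neurogranin, at 1060 ± 52.9 TPM. Also among the 15 highest were Aldoa, Actb, Calm2, Hspa8, Cpe, Eef1a1 and Glul, from 1056 ± 8.85 TPM for Aldoa to 889 ± 81.0 TPM for Glul. Of the genes from Camk2a to Aldoa, Camk2a was the highest in replicate 1 at 1176 TPM and the lowest in replicate 2 at 998 TPM. Their order was therefore not resolved. Gapdh, Snurf, Fth1, Aldoa, Actb, Calm2, Hspa8, Eef1a1 and Glul divided some reads with other genes. The level of Snurf rested on 2389 and 3138 expected counts, against 78493 and 91263 for Camk2a at a similar TPM. Its place therefore depends strongly on the length correction. Snap25 lies on chromosome 2 of the mouse genome build mm10, from 136713453 to 136782428 (ENSMUSG00000027273.13).

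In all, 14518 annotated genes had a TPM of at least 1 in both libraries. Of these 12767 (87.9%) were protein-coding, 453 were processed pseudogenes, 254 were long intergenic noncoding RNAs, 186 were antisense genes and 261 were TEC genes, mostly single-exon models that the annotation marks as still to be tested by experiment. Among the 12754 expressed nuclear protein-coding genes, 4725 had a mean below 10 TPM, 7157 lay between 10 and 100 TPM and 872 lay above 100 TPM. The count was 15716 in replicate 1 alone and 14784 in replicate 2 alone.

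Noncoding RNAs took the highest levels of all. Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle, each stood at 135903 ± 20670 TPM. Their values were equal in each library because reads were divided between identical copies, so neither copy's own level is known. Rn7sk, the 7SK RNA that holds back transcription elongation, followed at 60177 ± 2876 TPM, then the mitochondrial ribosomal RNAs mt-Rnr2 at 44466 ± 2551 TPM and mt-Rnr1 at 31025 ± 2540 TPM. Because these RNAs are short and TPM corrects for length, 7SL took 27.2% ± 4.13 of TPM but 3.74% ± 0.890 of expected counts. Nuclear protein-coding genes took 44.4% ± 3.56 of TPM and 80.0% ± 0.790 of expected counts. The 7SL share of TPM was 24.3% in replicate 1 and 30.1% in replicate 2, which alone lowers the TPM of every other gene in replicate 2, so ratios between the mice are given below from counts scaled by the trimmed mean of M-values (TMM).

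Markers of neurons, astrocytes and oligodendrocytes were present in both mice. The pan-neuronal list had a median of 447 ± 38.7 TPM and included Syp at 848 ± 0.0212 TPM and Map2 at 424 ± 49.4 TPM. A small SD in TPM does not show equal scaled counts, since Syp had a log2 ratio of 0.23 (replicate 2 over replicate 1) after TMM scaling. Nor does a larger SD show unequal ones, since Map2 had a log2 ratio of -0.012. The excitatory neuron list had a median of 64.9 ± 4.04 TPM, led by Camk2a and Nrgn, with Slc17a7, the cortical vesicular glutamate transporter, at 629 ± 19.7 TPM. The inhibitory neuron list had a median of 40.8 ± 2.96 TPM, with the somatostatin gene Sst at 191 ± 5.01 TPM, Lamp5 at 124 ± 15.98 TPM, the parvalbumin gene Pvalb at 51.1 ± 6.68 TPM and Vip at 28.7 ± 4.17 TPM. Astrocyte markers had a median of 54.5 ± 4.29 TPM and ranged from Sox9 at 9.78 ± 0.0778 TPM to the glutamate transporter gene Slc1a2 at 805 ± 140.5 TPM. Oligodendrocyte markers had a median of 111 ± 15.6 TPM, with the myelin gene Mbp at 785 ± 146 TPM, against 6.08 ± 0.0247 TPM for the precursor list, in which Pdgfra stood at 17.7 ± 1.48 TPM.

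Markers of vascular, immune and surface cell types were lower, apart from haemoglobin genes. The microglia list had a median of 18.4 ± 1.09 TPM, with P2ry12 at 22.5 ± 0.375 TPM. The endothelial list had a median of 17.6 ± 2.24 TPM and included the tight junction gene Cldn5 at 21.1 ± 2.05 TPM. The mural list stood at 6.34 ± 0.417 TPM and the meningeal fibroblast list at 5.50 ± 0.304 TPM, where Col1a1 had 9.14 ± 0.0919 TPM. Haemoglobin transcripts gave a red blood cell median of 200.4 ± 85.8 TPM and Hba-a1 at 216 ± 98.8 TPM. The near-identical haemoglobin genes divided reads, so the split between them is uncertain. Ependymal markers had a median of 1.06 ± 0.0495 TPM, while blood leukocyte markers stood at 0.0850 ± 0.0636 TPM, with at most 7 counts for any member in either library.

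Markers of the upper layers and of layers 4, 5 and 6 were present. The upper layer list (Cux2, Cux1, Calb1, Rasgrf2, Otof) had a median of 60.8 ± 3.24 TPM, with Cux2 at 83.0 ± 10.1 TPM. Layer 4 markers had a median of 19.6 ± 3.97 TPM, with Rorb at 26.2 ± 4.29 TPM. Layer 5 markers had 14.6 ± 1.41 TPM, with Fezf2 at 14.6 ± 1.41 TPM, and layer 6 markers 6.83 ± 1.29 TPM, with Tle4 at 20.3 ± 2.26 TPM. Markers of neighbouring regions differed in level. The striatum list stood at 12.2 ± 0.0849 TPM, although part of it is also made in cortex, such as Ppp1r1b at 84.6 ± 9.62 TPM and Penk at 53 ± 8.60 TPM, while Drd2 stood at 3.75 ± 0.297 TPM and Gpr6 at 2.90 ± 0.431 TPM. Thalamus markers had a median of 4.26 ± 0.396 TPM, hippocampus markers 0.830 ± 0.962 TPM, choroid plexus markers 0.540 ± 0.410 TPM, olfactory bulb markers 0.535 ± 0.233 TPM and hypothalamus markers 0.20 ± 0.0566 TPM. Medians of 18 of the 23 marker lists reached 1 TPM in both mice. The hippocampus median was 1.51 TPM in replicate 1 and 0.15 TPM in replicate 2, where its middle member Spink8 rested on 16 and 2 counts.

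**Figure D1:**
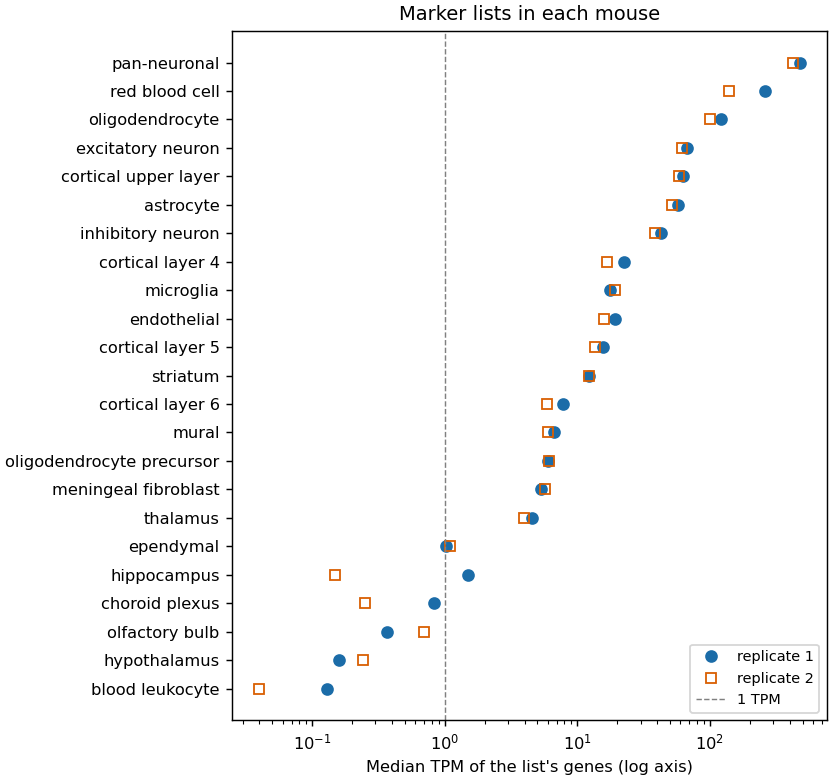
Median TPM (horizontal log axis) of each cell type or region marker list (vertical axis) in replicate 1 (filled circles) and replicate 2 (open squares), with a dashed line at 1 TPM. In all, 18 lists lie to the right of the line in both mice, from the pan-neuronal list at 447 ± 38.7 TPM down to the ependymal list at 1.06 ± 0.0495 TPM.

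Sex-linked transcripts were examined because the labels give both mice as female. Xist, the noncoding RNA made from the inactive X chromosome, stood at 62.9 ± 26.3 TPM (chromosome X, 103460366 to 103483254). Of the Y-linked genes, Ddx3y and Eif2s3y had 0 counts in both libraries, and Kdm5d and Uty had 1 count each in replicate 1 and 0 in replicate 2. The X escape list had a median of 59.7 ± 21.8 TPM.

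Transmitter receptor genes differed widely in level between subunits. The AMPA receptor list had a median of 90.3 ± 13.4 TPM and Gria2 exceeded Gria1 by a ratio of 2.30 ± 0.239 (SD, n = 2). The NMDA receptor list had a median of 16.8 ± 1.61 TPM, with the obligatory subunit gene Grin1 at 199.9 ± 24.1 TPM. Grin2a and Grin2b were nearly equal at 118 ± 28.0 and 119 ± 26.2 TPM, a ratio of 0.988 ± 0.0171. The GABA-A receptor list had a median of 38.6 ± 6.45 TPM. Kainate receptor genes had a median of 20.6 ± 3.31 TPM, with Grik5 highest at 93.6 ± 3.52 TPM. Slc12a5, the chloride extruder KCC2, was 13.0 ± 1.17 times as abundant as the chloride importer gene Slc12a2.

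Other fixed pairs separated cell types and partners. Slc17a7 exceeded Slc17a6, the vesicular glutamate transporter of thalamus and brainstem, 54.9 ± 15.05 times. Camk2a exceeded Camk2b 4.04 ± 0.310 times, Slc1a2 exceeded Slc1a3 5.99 ± 0.554 times and Gad1 exceeded Gad2 3.89 ± 0.284 times. Pvalb was lower than Sst at a ratio of 0.268 ± 0.0420, and Acan was lower than Vcan at 0.220 ± 0.00674. The ratio lay above 1 in both mice for 8 of the 12 pairs. In the second transcript table Grin2a/Grin2b was 1.23, so which partner was higher depended on the quantifier. The size of some ratios depended on the measure as well, with Slc1a2/Slc1a3 at 13.7 and Gad1/Gad2 at 1.71 in expected counts, which are not corrected for length, and at 4.61 and 2.72 in the second table.

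Extracellular matrix and neuropeptide genes were also measured. The perineuronal matrix list had a median of 28.0 ± 4.38 TPM, with Bcan at 110.1 ± 11.4 TPM and Ncan at 85.6 ± 5.996 TPM against 1.61 ± 0.304 TPM for Acan. The neuropeptide list had a median of 16 ± 1.61 TPM, led by Cck at 371 ± 19.6 TPM, Vgf at 152 ± 10.4 TPM and Npy at 103 ± 5.74 TPM.

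Each of the 19 genes examined for isoforms had the same leading transcript in both mice. It took 92.5% ± 0.852 of the TPM of the amyloid precursor gene App (SD, n = 2; ENSMUST00000005406.11, 16 exons), 85.7% ± 3.07 of Snap25 (ENSMUST00000028727.10, 8 exons), 74.6% ± 4.31 of the clathrin light chain gene Clta and 72.1% ± 1.53 of Mbp (ENSMUST00000133193.8, 5 exons). In the tau gene Mapt it took 70.0% ± 0.397. The share was 64.6% ± 0.632 in Camk2a, 60.4% ± 1.16 in Cdc42, 59.1% ± 2.00 in Dlg4, 57.3% ± 1.99 in Gnas and 55.3% ± 4.20 in Gria2. Pkm, a pyruvate kinase gene, was divided between a leading transcript at 51.0% ± 0.314 and a second one at 46.8% ± 1.17. No transcript reached 50% of Map2, Ntrk2, Grin1, Homer1 or Meg3. The leading transcript held at least 50% in both mice for 13 genes. The second quantifier put 9 genes past 50% and named the same leading transcript for 16, the exceptions being Grin1, Pkm and Meg3, and it gave the leading transcripts of Mbp and Dlg4 35.7% and 27.9%.

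The levels of most genes were close between the 2 mice. Across the 14518 expressed genes log2(TPM + 1) had a Pearson correlation of 0.989 and a Spearman correlation of 0.987; these are correlations across genes, which are not independent replicates. In TPM, 89.7% of these genes lay within 1.5-fold of each other, and 92.8% of the nuclear protein-coding ones. Beyond counting noise, genes varied between the 2 libraries with a biological coefficient of variation of 12.3% over 18187 genes. It was 2.71% for the 25 spike-ins with a mean of at least 100 reads. With 1 library per mouse, the value for genes cannot be divided between the mice and the handling of tissue and RNA. Spike-ins do not come from the tissue, so their lower value does not make that division. Spike-ins took 0.349% of expected counts in replicate 1 and 0.461% in replicate 2. Scaling by spike-ins in place of TMM gave a coefficient of variation of 0.274 as a fraction, and the median log2 ratio of all genes was -0.44 in place of 0.022.

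**Figure D2:**
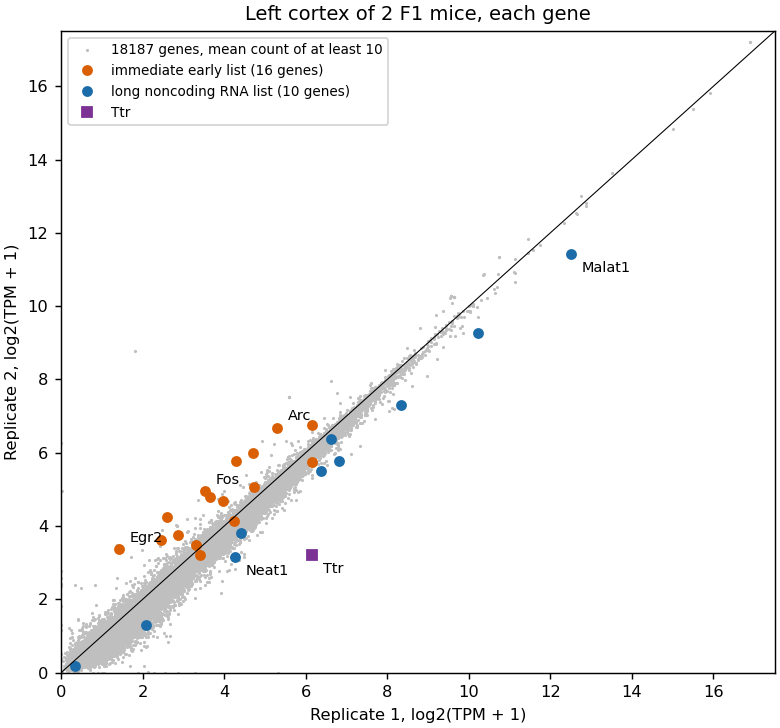
Log2(TPM + 1) of each of 18187 genes in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with the line of equal values; orange circles are the 16 immediate early genes, blue circles the 10 long noncoding RNAs of the fixed list and the purple square Ttr. Most immediate early genes lie above the line and most of these long noncoding RNAs below it, with median log2 ratios of 1.38 and -0.80 after TMM scaling.

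Immediate early genes, which neurons switch on within minutes of activity, were higher in replicate 2. Of the 16 genes on that list, 15 were higher in replicate 2 and 9 by at least 2-fold, with a median log2 ratio of 1.38 (replicate 2 over replicate 1). Egr2 had a log2 ratio of 2.25 (95% counting interval 1.94 to 2.61, from 89 and 491 counts), Btg2 2.07 (1.88 to 2.28), Fos 2.01 (1.84 to 2.21), Junb 1.79 (1.67 to 1.93) and Arc 1.64 (1.58 to 1.71). Ier2, Dusp1, Nr4a1 and Npas4 followed at 1.56, 1.52, 1.498 and 1.26. Egr4, Egr1 and Jun stood at 0.99, 0.85 and 0.59, while Nr4a3, Fosb, Fosl2 and Egr3 had ratios of 0.24, 0.14, 0.024 and -0.16. Fos lies on chromosome 12 (ENSMUSG00000021250.13, 85473890 to 85477273), Egr2 on chromosome 10 (ENSMUSG00000037868.15, 67535475 to 67542188) and Arc on chromosome 15 (ENSMUSG00000022602.14, 74669083 to 74672570). The list lay at percentile 100 of 10000 random lists matched on mean expression, whose central 95% ran from -0.059 to 0.14. Under spike-in scaling, which moves all genes and so the random lists by about the same amount, its median was 0.91. Each mouse is 1 library, so the difference has no replicate check.

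Across the whole transcriptome 90 of 12615 genes with a mean count of at least 100 stood 2-fold or more apart, 35 higher and 55 lower in replicate 2. Outside the immediate early list the higher genes included the matrix protein gene Ccn1 at 2.04 (1.71 to 2.43, from 81 and 387 counts), Ndst4 at 1.63, Gadd45g at 1.43 and Baiap3 at 1.40. Ccn1, Ndst4, Gadd45g and Baiap3 are not among the 10 highest and were chosen after their values were seen, as protein-coding genes with whole counts and a ratio of at least 2-fold. The lower genes were led, among those with whole counts, by Ttr, the transthyretin gene of choroid plexus, at -2.82 (-3.04 to -2.63, from 1424 and 228 counts; chromosome 18, 20665280 to 20674321). TEC genes made up 36 of the 55 lower genes, among them Gm44518 at -1.42, Gm49069 at -1.37, Gm42993 at -1.32, Svet1 at -1.32 and Gm45191 at -1.28, and sense intronic genes made up 3.

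For 30 of the 90 genes the expected counts were not whole in at least 1 library, so reads were divided with other genes and the ratio is uncertain. They include Gm14440 at -6.27, 1700047I17Rik2 at -2.45, Gm2004 at -1.38, Gm11847 at -1.32, Gm24497 at 7.25 and Gm20388 at 4.14, and 4 copies of the U3 small nucleolar RNA, Rnu3b1 to Rnu3b4, with equal ratios of 2.18. Rpl7a-ps11, a pseudogene with divided reads, was at least 155-fold higher in replicate 2, against a floor of 3 counts where replicate 1 rounded to 0. Rnu3a, another U3 copy, had whole counts of 0 and 220 and was at least 64.2-fold higher on the same floor, but it held no reads in the second transcript table, which leaves this ratio uncertain too. Of the 90 genes, 43 were again 2-fold or more apart in the same direction in the second transcript table, 15 higher and 28 lower, while 1700047I17Rik2 changed sign to 0.36, and Gm20388 and Gm2004 shrank to 0.39 and -0.10. Spike-in scaling gave 306 genes, 22 higher and 284 lower.

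Several other gene groups differed between the mice. The fixed list of 10 long noncoding RNAs, of which Snhg11 is annotated as protein-coding, was lower in replicate 2, with all members below a ratio of 0 and a median of -0.80. The wider class moved less at the median, since the 548 annotated long intergenic noncoding RNAs with a mean count of at least 10 had -0.15 (quartiles -0.48 and 0.15), with 64.6% lower in replicate 2. The summed log2 ratio of the class, -0.075, follows genes with many counts. Among them were Gm26917 at 0.32 (598325 and 851352 counts) and Gm42418 at 0.086 (244242 and 296193 counts), both chosen after their values were seen. The sum therefore does not describe most genes of the class. Within the list Neat1 had a log2 ratio of -1.04, Malat1, an abundant RNA retained in the nucleus, -0.95 (-0.95 to -0.94), Kcnq1ot1 -0.88 and Meg3 -0.84, while Peg13 was near 0 at -0.00715. Meg3, Miat, Rmst, Neat1, Kcnq1ot1 and Tsix divided some reads with other genes. The TEC class was lower as well, with a median of -0.73 over 1253 genes (quartiles -1.04 and -0.40), of which 91.0% were lower in replicate 2. Red blood cell markers had a median of -0.66, with all 5 lower, Hba-a1 at -0.75 and Alas2 at -0.22. Choroid plexus markers had a median of -1.48 over the 4 members with a mean count of at least 10, Ttr, Clic6, Aqp1 and Kl, at -2.82, -1.56, -1.39 and -0.40. Glucocorticoid-responsive genes had a median of -0.20, with 7 of 9 lower, Plin4 at -1.01, Zbtb16 at -0.60, Fkbp5 at -0.33 and, in the other direction, Sgk1 at 0.31.

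Higher in replicate 2 were the striatum list, with a median of 0.40 and 8 of 9 members above 0, the microglia list at 0.19 and the olfactory bulb list at 0.97. Penk, Gpr6, Ppp1r1b and Adora2a had ratios of 0.53, 0.54, 0.51 and 0.51, and Pde10a had -0.051. The olfactory bulb median rested on 3 genes, Cdhr1 at 0.98 from 214 and 486 counts, Th at 0.97 from 12 and 29 counts and, in the other direction, Doc2g at -0.36. With a minimum mean count of 1 that median was -0.13 at percentile 39.1. The microglia list lay at percentile 97.9 and, in the second transcript table, at percentile 95.005. Under spike-in scaling the striatum and microglia medians were -0.061 and -0.28, against -0.44 for all genes.

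Of the 37 lists with at least 3 usable genes, 8 lay outside the central 95% of their matched random lists. For independent lists of unrelated genes the number would be 1.85. Genes within a list can vary together, and some lists share members such as Meg3, so 1.85 is not the number to be expected for these lists. Glucocorticoid-responsive genes lay at percentile 0.150, and at 2.96 against random lists that were not matched. The other marker and functional lists lay inside, although the hypothalamus list reached percentile 99.5 against random lists that were not matched and the mitochondrial mRNA list 97.8 in the second transcript table. Their medians included 0.10 for pan-neuronal, 0.052 for excitatory neuron, 0.00133 for inhibitory neuron, 0.13 for astrocyte and -0.071 for oligodendrocyte genes. AMPA receptor genes stood at -0.10, NMDA receptor genes at 0.023, GABA-A receptor genes at 0.019 and neuropeptide genes at 0.13. Circadian clock genes had a median of 0.10, with Dbp at 0.56, Per1 at 0.39 and Arntl at -0.30. Of these clock genes 8 were higher and 6 lower in replicate 2. Members that move in opposite directions cancel in a median, so its place inside the range does not show an unchanged clock. Heat shock genes had 0.058 and interferon response genes 0.13.

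**Figure D3:**
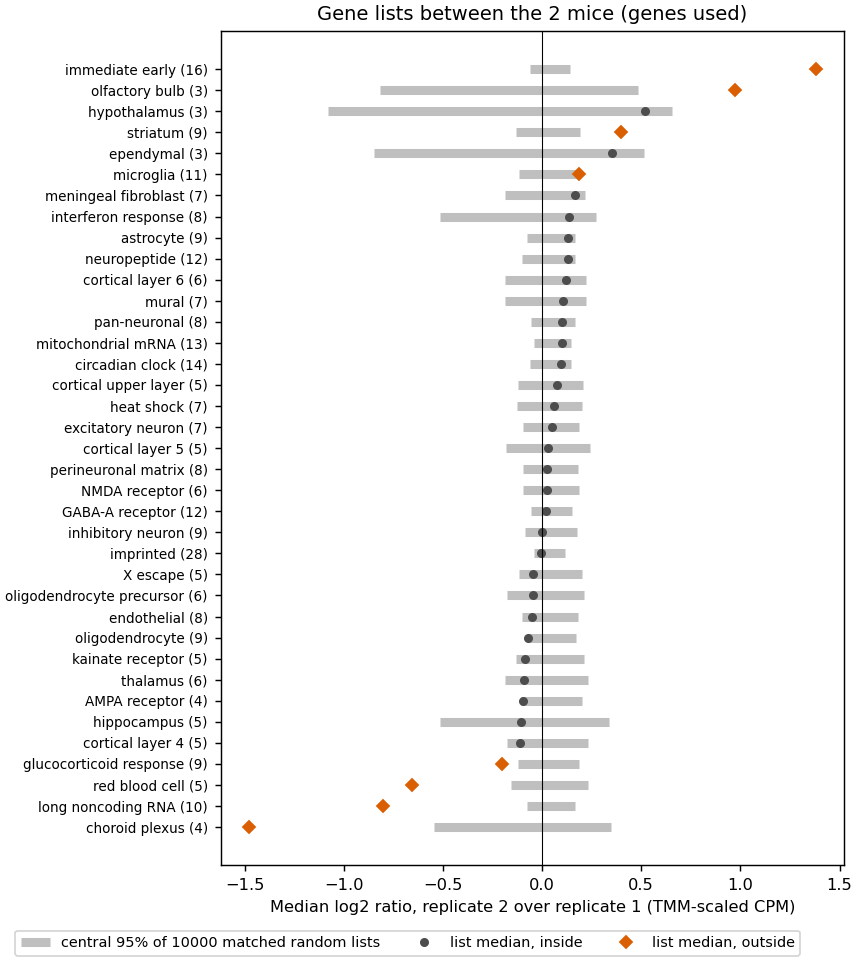
Median log2 ratio of replicate 2 over replicate 1 (horizontal axis, TMM-scaled CPM) of each gene list (vertical axis, genes used in brackets), as a grey circle inside or an orange diamond outside the central 95% of 10000 matched random lists (grey bars). The 8 diamonds run from the choroid plexus list at -1.48 to the immediate early list at 1.38.

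The same reads were deposited as 2 transcript tables, and gene levels from them were close but not equal. Between the tables, summed to genes, log2(TPM + 1) had a Pearson correlation across genes of 0.974 ± 0.00577 (SD, n = 2), and 11.2% of genes in replicate 1 and 17.9% in replicate 2 lay more than 2-fold apart in TPM. In every length class of protein-coding genes the TPM of the second table was higher at the median, with ratios of 1.43 to 1.63 in replicate 1 and 1.58 to 1.81 in replicate 2, and this common offset was not removed from the 2-fold comparison. The second table gave short transcripts fewer reads. Protein-coding genes under 500 bases had a median read ratio, second over first, of 0.731 in replicate 1 and 0.724 in replicate 2, against 1.10 and 1.09 for genes over 4000 bases. The 7SK RNA Rn7sk had a mean of 3.31 TPM in the second table against 60177 TPM in the gene table, so its ratio between the mice in the second table is not given. Of the spike-ins, ERCC-00171, 505 bases long, had 2296 reads in the first table and 1094 in the second in replicate 1, and ERCC-00025, 1994 bases long, had 186 and 168.

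**Figure D4:**
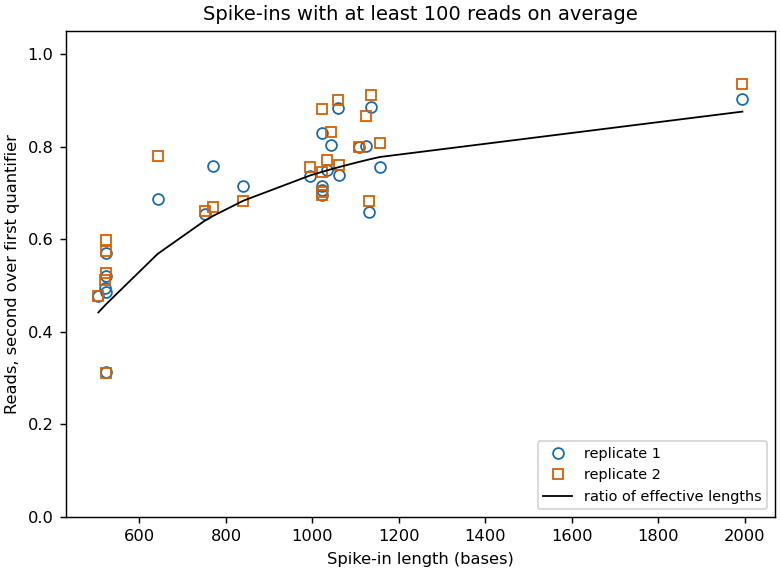
Ratio of reads in the second over the first quantifier (vertical axis) against length in bases (horizontal axis) for the 25 spike-ins with a mean of at least 100 reads, in replicate 1 (circles) and replicate 2 (squares), with the ratio of effective lengths as a line. Mean ratios run from 0.312 for ERCC-00046, of 522 bases, to 0.920 for ERCC-00025, of 1994 bases.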

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

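The rows of the gene table named only by number, which no comparison uses, held 5.89 expected counts in replicate 1 in total, above the 3 counts that a count of 0 allows. In replicate 2 they held 2.92, below that limit.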

How the results depend on the processing

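Counts of expressed genes, of lists outside the random range, of marker lists above 1 TPM, of pairs above 1 and of isoforms past 50% stayed within 1.5 times their main values under every alternative run. Expressed genes ranged from 10490 at a minimum of 5 TPM to 20875 at 0.1 TPM. Genes 2-fold apart, 90 as reported, numbered 306 with spike-in scaling, 2422 with no filter, 734 at a minimum count of 10, 5 at 1000 and 389 at 1.5-fold, where the filter and fold follow from their own construction. With spike-in scaling, which applies 1 factor to each library, the median of all genes was -0.44 in place of 0.022. The Pearson correlation between mice was 0.987 with a pseudocount of 0.1, 0.986 with 0.01, 0.993 with no filter, 0.988 at 5 TPM and 0.988 in the second transcript table. The share within 1.5-fold was 71.2% with no filter, 95.02% at 5 TPM, 94.7% in FPKM and 86.6% in the second table. The coefficient of variation, 0.123 as a fraction, was 0.125 with total counts and 0.274 with spike-ins. Further settings, chosen after seeing the data, gave 0.125 at a minimum count of 1, 0.108 at 100 and 0.145 in the second table. Correlation between the transcript tables was 0.935 with no filter. For these the cause was not tested.

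Among lists outside the random range, signs changed for the microglia median at -0.28 and the striatum median at -0.061 with spike-ins, both above that median of all genes, and for the olfactory bulb median at -0.13 with a minimum count of 1. A scaling moves all genes, and so the random lists, by about the same amount, so sign changes of lists under another scaling follow from that common shift and percentiles kept under it are no support. Lists inside the range changed sign as well, such as ependymal at -0.072 in the second table and imprinted at 0.083 with protein-coding genes only. They also changed for Grin2a/Grin2b at 1.23 and 1700047I17Rik2 at 0.36 in the second table, and apart from the changes with spike-ins the cause was not tested. Gm20388 and Gm2004 weakened to 0.39 and -0.10 in the second table. In expected counts the ratios of pairs were 13.7 for Slc1a2/Slc1a3, 1.71 for Gad1/Gad2, 8.97 for Slc12a5/Slc12a2, 1.97 for Gria2/Gria1, 0.589 for Grin2a/Grin2b, 0.376 for Pvalb/Sst and 0.251 for Acan/Vcan. The second table held no reads for 9 of the genes fixed by rule, which gave no value there. No paired analysis was possible because the series has 1 group. Depth limits ratios of genes near 100 counts.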

Other observations

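Imprinted genes, which in at least some tissues are expressed mainly from 1 parental copy, covered a wide range of levels in this cortex. The list had a median of 32 ± 6.32 TPM. Within the list Meg3 led with 912 ± 413 TPM, followed by Gnas at 774 ± 1.27 TPM, Rian at 489 ± 157 TPM and Snrpn at 414 ± 33.5 TPM, while H19 stood at 0.155 ± 0.00707 TPM and Magel2 at 0.370 ± 0 TPM. A transcript of 457 bases took 27.1% of the TPM of Meg3 but had no share of it in the second transcript table. The imprinted gene Snurf, at 1076 ± 22.4 TPM, is not on the list. Between the mice the list had a median log2 ratio of -0.00348, with 14 genes higher and 14 lower in replicate 2, including Nnat at 0.87 and the noncoding Mirg at -0.68. Whether each parental copy was used cannot be read from these tables, which hold no allele counts.

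Mitochondrial messenger RNAs had a median of 1905 ± 419 TPM, led by mt-Co1 at 6155 ± 205 TPM and mt-Cytb at 3364 ± 137 TPM, and a median log2 ratio of 0.10. The low level of mt-Co2, 173 ± 106 TPM, stood beside 7362 ± 283 TPM for the pseudogene Gm28661 on chromosome 1. Next to it lie the pseudogenes Gm10925 at 6167 ± 397 TPM and Gm28437 at 5020 ± 151 TPM. The rule for naming genes does not cover these 3 pseudogenes, which were chosen after the data were examined. All 3 had expected counts that were not whole, so reads were divided with other genes. On the mitochondrial list the same held, in at least 1 library, for mt-Co1, mt-Co2, mt-Co3, mt-Atp6 and mt-Nd4l, but not for mt-Cytb. The order of the levels on this list and its medians are therefore uncertain. Which genes shared reads with which was not tested. The ratio of 1.59 for mt-Co2 was 0.23 in the second transcript table. Short structural RNAs were higher in replicate 2, with summed log2 ratios of 0.88 for small nuclear RNAs, 0.55 for 7SL and 0.15 for 7SK, although with spike-in scaling, which moved the median of all genes to -0.44, the ratio of the 7SK gene Rn7sk was below 0. The remaining lists had medians of -0.052 (endothelial), 0.10 (mural), -0.045 (oligodendrocyte precursor), 0.17 (meningeal fibroblast), 0.35 (ependymal, over 3 genes, and -0.072 in the second transcript table), 0.075 (upper layer), -0.11 (layer 4), 0.028 (layer 5) and 0.12 (layer 6). Medians were -0.094 for thalamus, -0.11 for hippocampus, 0.52 for hypothalamus, -0.087 for kainate receptor, 0.026 for perineuronal matrix and -0.044 for X escape genes.

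The 3 patterns below were noticed in the data first, the tests were set before their values were seen, and 1 test, of the density of reads over silent genes, was chosen after seeing the data. Immediate early genes were higher in replicate 2, with a median log2 ratio of 1.38. A GC content or length trend was argued against, since after correction the median was 1.28, above the -0.085 to 0.089 of random lists. A different share of neurons was argued against, since the larger of the pan-neuronal and excitatory neuron medians was 0.10. A stress response that also raises glucocorticoid-responsive genes was argued against, since that list had a median of -0.20, with 7 of 9 genes lower. The 2 higher genes included Sgk1 at 0.31. These values speak only to a stress response that had already raised such genes when the tissue was taken. They do not exclude a more recent one or other kinds of stress. Differences in activity or handling of the animals before death were not tested and stay open.

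TEC genes, 1247 of 1253 of them with a single exon and 969 of them inside a protein-coding gene on the same strand, were lower in replicate 2, with medians of -0.81 inside such genes and -0.41 outside. The 135 sense intronic genes were lower to a similar degree at the median, -0.71, although their summed ratio was -0.30. The tests below were run on TEC genes only. Genomic DNA in replicate 1 was tested on olfactory and vomeronasal receptor, keratin-associated and defensin genes, whose summed log2 ratio was -0.57 (95% counting interval -0.70 to -0.44), only just above the TEC median of -0.73 and overlapping the summed TEC ratio of -0.68, but their read density would give 1.87% of the TEC reads in replicate 1, against 37.6% fewer in replicate 2. A GC content or length trend left a TEC median of -0.69 after correction. A lower share of nuclear RNA in replicate 2 may explain part of the pattern, since the 9 members of the long noncoding RNA list without Malat1 had a median of -0.78, within the TEC quartiles. That support rests on a few chosen genes, and all 548 long intergenic noncoding RNAs, nuclear or not, had a median of -0.15, nearer 0 than the TEC quartiles of -1.04 and -0.40. Short nuclear RNAs also go against it as the whole explanation, since summed small nuclear RNAs, small nucleolar RNAs and 7SK were higher in replicate 2 at 0.88, 0.58 and 0.15, as was the cytoplasmic 7SL at 0.55. For small nucleolar RNAs the sum includes U3 copies with uncertain ratios. The median of that class was 0.38 over 56 genes, with 25% of them lower in replicate 2. Differences in RNA recovery by size, RNA quality and ribosomal RNA removal were not tested and stay open, and no biological explanation was tested.

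The second quantifier gave fewer reads to short transcripts. Dropped reads whose fragment would not fit in the transcript may be the source, since over 24 spike-ins the log2 ratio of reads followed the log2 ratio of effective lengths with a slope of 0.94 (SE 0.131). That support covers spike-ins only. Protein-coding genes of 500 to 1000 bases had median read ratios of 0.972 in replicate 1 and 0.958 in replicate 2. Spike-ins of 521 to 994 bases had mean effective length ratios of 0.458 to 0.738, so at the median these genes lay above that line. A strand or index difference that affects all spike-ins alike would not give the trend of the spike-ins with length. It stays open as a further loss, since the 14 spike-ins over 1000 bases had a median ratio of 0.791 while protein-coding genes of 1000 to 2000 bases had 1.04 in replicate 2, and the limit of 0.7 set for this test could not tell such a loss from none.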
